A study of Kluyveromyces lactis with 6 samples.

How the data were processed

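Expression was measured by RNA-seq in the budding yeast *Kluyveromyces lactis*. Total RNA was taken by hot phenol, followed by DNase treatment, a column clean-up and a TruSeq kit that does not keep the strand. Reads of 50 bp were taken from 1 end of each fragment on an Illumina HiSeq instrument, per the labels' protocols. Cultures grew at 30 °C in rich glucose medium (1% yeast extract, 2% peptone and 2% glucose), and 10 OD of cells were taken early in log phase. The 6 libraries came from 3 strains: a wild type (LRY2835) and 2 isolates of a *sir2* deletion (LRY2849 as isolate 1 and LRY2850 as isolate 2). By their genotype labels, all 3 strains are *MATa* with both silent mating cassettes, *HML* and *HMR*, deleted. The series' design text calls the 2 libraries of a strain technical replicates.

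The authors deposited 1 FPKM value (fragments per kilobase of gene, scaled to the mapped total) per gene and library, for 5076 genes. TopHat2 2.0.10 and Cuffnorm 2.2.1 were used, per the submitters' processing notes. The genome build, the annotation and the scaling option of Cuffnorm are not given in the sources used here. Cuffnorm values are estimates, so reads of near-identical genes can be divided between copies, and the kit cannot separate a gene from an antisense partner. The sum of FPKM ran from 1542502 to 1803539 per library, which is not a depth. Low values moved in steps: a gene with a coding length of 1524 nt was listed at 0.0429 in 1 library of isolate 1 and at 0.0375 in 1 library of isolate 2. The estimates are fractional, however, and whole reads could not be recovered, so the number of reads is unknown and no counting interval is given.

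All 5076 identifiers matched the RefSeq table of assembly ASM251v1 (strain NRRL Y-1140), and 3959 had a gene symbol there. That table was used for symbols, coding lengths and the order of genes only, and no coordinates are given because the build behind the values is not stated. *SIR2* has no symbol in the table: KLLA0F14663g was taken as *SIR2* from general knowledge of the species' gene names before its values were seen.

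Values were analysed as log2(FPKM + 1), which understates changes of genes near 0. For sir2Δ against WT, the 2 technical libraries of each strain were averaged, and 1 WT strain was compared with 2 sir2Δ isolates in limma 3.58.1 (R 4.3.3) with an intensity trend. The fit had 1 residual degree of freedom per gene and a prior of 7 degrees of freedom. WT is 1 culture, so it was assumed to vary like the isolates. The 5021 genes with a mean of at least 1 FPKM over the strain means were tested, leaving out 55, and an adjusted p (Benjamini-Hochberg, two-sided) under 0.05 was the threshold. Contrasts involving single isolates came from a limma fit of the 6 libraries in 3 strain groups with 3 residual degrees of freedom. Its p-values measure only the spread between technical libraries, and both isolates are set against the same WT libraries, so no overlap between them is read as independent.

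Gene lists, 18 in number, were fixed before the data were examined, and a list of the 10 terminal annotated genes of each of the 12 chromosome arms was added as the subtelomeric list under the same plan. Members of the 18 lists were matched by gene symbol alone, and names without a match were left out. Each of the 19 lists was tested with camera in limma at a preset inter-gene correlation of 0.01, with adjustment over the 19 lists. Subtelomeric calls were also compared with all other tested genes by Fisher's exact test, which treats genes as independent. Runs of 3 or more neighbouring tested genes that passed in the same direction were counted against 10000 random gene orders (one-sided permutation test). The genes named are *SIR2*, the 15 largest rises and 15 largest falls among passing genes whose sir2Δ libraries all lay on the same side of both WT libraries, the 2 highest and 2 lowest members of each list, and the 5 largest differences between isolates in each direction. Further members are named as examples after their values were seen.

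The procedure was tested on simulated data: 20 simulated sets of the 5021 genes with 200 changed genes each. It recovered 83.1% of genes changed by 1 on the log2 scale, 96.9% at 1.5 and 99% at 2. False calls made up 10.4% of calls on average, between 2.7% and 24.7% in single sets, against a nominal 5%. In these sets the test therefore called more false genes than its threshold states. The false share and the recovery depend on how many genes change, and the real data gave 2013 calls, so neither carries over directly. The simulation was revised once, because an earlier version counted technical noise a second time and gave a higher share; the fit was not changed. Of unchanged simulated lists, 0.2% passed an unadjusted camera p of 0.05. The simulated genes varied independently, so this share says nothing about lists whose genes vary together. In the real data the correlation estimated over all libraries ran from 0.013 (histones and DNA replication) to 0.819 (hexose transport and glycolysis). For ribosome biogenesis it was 0.325.

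Alternatives tried were 3 other pseudocounts, other filters, 2 other scalings, 4 treatments of the technical libraries, other variance settings, a 2-fold limit, each isolate alone, each library left out, other subtelomere and run definitions, and other list tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Other splits of the samples were not counted, since WT holds 2 libraries of 1 strain.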

Results

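RNA from *K. lactis* cells with and without *SIR2*, which encodes an NAD+-dependent histone deacetylase of silent chromatin, was measured in 6 libraries: 2 of WT, 2 of sir2Δ isolate 1 and 2 of sir2Δ isolate 2. The comparison asks which genes differ when *SIR2* is absent. Technical pairs had Pearson r across genes of 0.999, 0.996 and 0.997 on log2(FPKM + 1), and the SD of their difference was 0.11, 0.18 and 0.17. Libraries of the 2 isolates correlated at 0.990 to 0.993, and sir2Δ with WT libraries at 0.887 to 0.905. Genes are not independent replicates in these correlations. *SIR2* (KLLA0F14663g) was at 66.9 and 64.9 FPKM in WT, at 0.0916 and 0.0845 in isolate 1 and at 0.108 and 0.0503 in isolate 2, as the labels state.

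Loss of *SIR2* went with broad change. In sir2Δ, 1013 of 5021 tested genes were higher and 1000 were lower than in WT (limma, adjusted p under 0.05), which is 40.1% of those tested. Large changes were mostly rises: 457 genes rose and 308 fell at least 2-fold, and 95 rose at least 8-fold against 2 that fell as much, *SIR2* and *ADH3*. In 2009 of the 2013 called genes all sir2Δ libraries lay on the same side of both WT libraries. The calls came from these same libraries and technical pairs differ little, so this count is no separate support. WT was 1 culture, so strain, culture and genotype differ together in every comparison with it. Simulated data gave more false calls than the nominal share (10.4% against 5%). Those sets held 200 changed genes each, far fewer than the 2013 called here, so 10.4% does not estimate the false share of these calls.

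The largest rises started from low WT levels. KLLA0F05379g went from 1.02 FPKM in WT to 166 and 189 in isolates 1 and 2 (log2 change 6.46, SE 0.17, adjusted p = 3.2e-07 in limma), and KLLA0F24486g from 2.23 to 224 and 228 (6.13). Others without a symbol were KLLA0C17226g (6.19), KLLA0F24596g (6.06), KLLA0C05456g (5.92), KLLA0A05687g (5.83), KLLA0E19295g (5.54), KLLA0A00132g (5.49), KLLA0C06677g (5.14) and KLLA0B09042g (5.11). KLLA0D09218g was listed at 0 in both WT libraries and averaged 43.5 and 41.2 FPKM in the isolates. Named genes among the 15 were *MOH1* (5.73), *AGA2*, a subunit of the a-agglutinin of mating cells (5.68), *PFS1*, needed for prospore membrane formation (5.63), and *RRT8* (5.50).

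After *SIR2*, the alcohol dehydrogenase gene *ADH3* fell furthest, from 595 FPKM in WT to 50.4 and 90.4 (log2 change −3.12, SE 0.29). *FAF1* and *RCM1*, both of ribosome assembly, changed by −2.92 and −1.89, and the ribosomal protein gene *RPL9B* by −2.26. *PDR12*, a weak acid exporter, changed by −2.44, *ERG1*, squalene epoxidase of sterol synthesis, by −1.895, the cyclin gene *PCL1* by −1.86 and *SER2* of serine synthesis by −1.855. *SDA1* and *TRM44* (−1.87 and −1.80) and the unnamed KLLA0E14477g (−2.59), KLLA0E05897g (−1.99), KLLA0A07777g (−1.86) and KLLA0F07073g (−1.82) complete the 15.

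**Figure D1:**
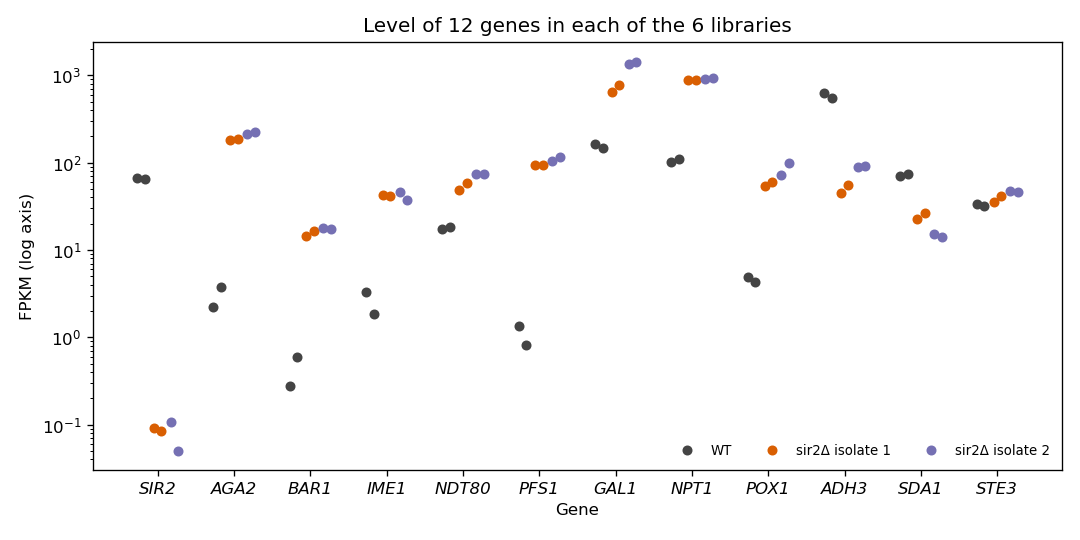
FPKM of 12 genes (x axis) in each library on a log axis, with WT in grey, sir2Δ isolate 1 in orange and isolate 2 in purple, 1 point per library. *SIR2* lies under 0.11 FPKM in all sir2Δ libraries, *AGA2* rises from 2.99 to 184 and 218 on average and *ADH3* falls from 595 to 50.4 and 90.4; *STE3* did not pass.

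Sporulation genes were higher in sir2Δ cells taken in early log phase. Of 31 tested genes of middle sporulation and spore wall formation, 25 were higher and 0 lower (median log2 change 1.88; 26 higher and 1 lower adjusted over the list alone). The camera adjusted p was 2.7e-12, and the adjusted p = 0.769 with an estimated correlation. *SSP2*, needed for spore wall assembly, changed by 4.72 (SE 0.25), *GIP1* by 4.06, *CRR1* by 3.90 and *NDT80*, the transcription factor of middle sporulation genes, by 1.78. *CHS3* (−0.53) and *SHC1* (−0.53), chitin synthesis genes, were at the low end and did not pass. Early meiosis and recombination genes numbered 14 higher, 1 lower and 13 not passing of 28 (median 0.75; 17 higher and 1 lower adjusted over the list alone; camera adjusted p = 8.1e-05, adjusted p = 0.769 with an estimated correlation). *IME1*, the inducer of meiosis, went from 2.57 FPKM to 42.2 and 41.4 (3.61, SE 0.19), *NDJ1* rose by 2.85 and *SPO11*, the meiotic double-strand break enzyme, by 1.81. *SPO13* was lower (−0.85), and *MSH5* did not pass (−0.34).

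Markers of mating type moved unequally. The a-cell and alpha-cell list also holds *AXL1*, *KEX2*, *STE13* and *STE14*, which are not specific to 1 mating type in *Saccharomyces cerevisiae*. Among its 11 tested genes 4 were higher and 0 lower, the same counts adjusted over the list alone (median 0.36, camera adjusted p = 0.0314, adjusted p = 0.819 with an estimated correlation). They were *AGA2*, *BAR1*, which encodes the protease that degrades alpha-factor (3.62, SE 0.28), *AXL1* (1.21) and *ASG7* (0.89). The pheromone receptor genes *STE2* (−0.23) and *STE3* (0.36) and the alpha-agglutinin gene *SAG1* (0.07) did not pass. With genes of at least 10 FPKM on average the list's adjusted p was 0.102. In the pheromone response and haploid-specific list, 10 of 24 were higher and 3 lower (10 and 4 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.133). *STE18*, the gamma subunit of the pheromone G protein, rose from 1.69 FPKM to 43.9 and 47.5 (4.15), and *PRM1* by 2.31, while *STE50* fell by 0.62 and *CLN3* (−0.75) did not pass.

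Genes of respiration and of growth on carbon sources other than sugar were higher. Of 25 genes of gluconeogenesis, the glyoxylate cycle and fatty acid oxidation, 19 were higher and 1 lower (median 1.61; 20 and 1 adjusted over the list alone; camera adjusted p = 2.7e-09, adjusted p = 0.769 with an estimated correlation). *POX1*, acyl-CoA oxidase, changed by 3.65 (SE 0.24), *ALD4*, a mitochondrial aldehyde dehydrogenase, by 3.41 and *MLS1*, malate synthase, by 2.21, while *ACS2*, acetyl-CoA synthetase, fell by 0.96. *YAT2* did not pass (−0.42). Respiration and TCA cycle genes were higher in 29 of 44 and lower in 0 (median 0.66; 32 higher adjusted over the list alone; camera adjusted p = 8.1e-10, adjusted p = 0.769 with an estimated correlation). *CIT3* (3.08) and *SDH2* (2.25) led, and *ATP20* (0.01) and *ATP7* (−0.04) did not pass. The galactose and lactose list had 4 of 7 higher and 0 lower, alike adjusted over the list alone (median 0.60; camera adjusted p = 0.0356, adjusted p = 0.844 with an estimated correlation): *GAL10* (2.90), *GAL1* (2.67), *MIG1* (1.27) and *GAL4* (0.60). *GAL7* (0.29) and *SNF1* (−0.38) did not pass. Symbols matched only 7 genes to the 19 names of this list, and 9 to the 38 names of the hexose transport and glycolysis list. Both lists therefore cover their pathways only in part. Matches were also partial for other lists, among them 11 genes for 21 names of NAD+ biosynthesis and salvage. The a-cell and alpha-cell list had 11 genes for 22 names, and the transporter list 23 for 64. With the 6 libraries entered singly in 2 genotype groups, the galactose and lactose list missed the threshold in the planned fit with the replicate number as a block (camera adjusted p = 0.0836) and in a fit without the block that was added after seeing the data (0.0827). In the hexose transport and glycolysis list 3 of 9 were lower, *ADH3*, *GPM1* (−0.76) and *ADH4* (−0.47), with 1 lower adjusted over the list alone, and *FBA1* (0.11) and *PGI1* (−0.07) did not pass. That list missed the threshold (camera adjusted p = 0.0984) and passed it after quantile normalization (0.0374) and without isolate 1 replicate 2 (0.022). Without isolate 2 replicate 1, *GPM1* had an adjusted p of 0.0568.

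Ribosome biogenesis genes fell almost throughout. Of 95 tested, 92 were lower and 0 higher (median −1.13; 94 lower adjusted over the list alone; camera adjusted p = 1.79e-21, adjusted p = 0.819 with an estimated correlation). *SDA1* (−1.87) and *DBP8* (−1.79) were lowest, and *UTP8* (−0.39) and *TIF6* (−0.40) did not pass. Cytosolic ribosomal protein genes changed less: 8 of 57 were lower and 0 higher (median −0.34; 3 lower adjusted over the list alone; camera adjusted p = 0.00045, adjusted p = 0.844 with an estimated correlation). Among all tested genes 1000 of 5021 were lower, a larger share, so the count of 8 shows no excess of falls. *RPL9B* and *RPL28* (−1.13) were lowest, and *RPP2A* (0.20) and *RPL10* (0.14) did not pass.

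Genes of NAD+ biosynthesis and salvage, which make the cofactor of Sir2, were higher in 5 and lower in 1 of 11, the same counts adjusted over the list alone (median 0.29; camera adjusted p = 0.0182, adjusted p = 0.844 with an estimated correlation). *NPT1*, nicotinate phosphoribosyltransferase, rose from 106 FPKM to 880 and 916 (3.08, SE 0.14) and *TNA1*, the nicotinic acid transporter, from 223 to 902 and 1119 (2.16, SE 0.17). *BNA3* was lower (−0.53), and *POS5* did not pass (−0.10). *TNA1* also stands in the list of drug, vitamin and polyol transporters, where 11 of 23 were higher and 2 lower (median 0.45; 12 and 2 adjusted over the list alone; camera adjusted p = 0.0137, adjusted p = 0.819 with an estimated correlation). *THI2* (3.52) was highest there, and *PDR12* and *BIO2* (−1.07) were the 2 lower genes.

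The other lists did not pass. Silencing and chromatin genes, 30 without *SIR2*, had 3 higher and 6 lower (1 and 3 adjusted over the list alone; camera adjusted p = 0.0984), with *HOS1* (0.82) and *SUM1* (0.54) highest and the histone chaperone gene *ASF1* (−1.52) and *FOB1* (−0.98) lowest. *SUM1* missed the threshold without isolate 1 replicate 2 (adjusted p = 0.0546) and without isolate 2 replicate 1 (0.0673). Heat shock and general stress genes had 10 higher and 8 lower of 30 (13 and 9 adjusted over the list alone; camera adjusted p = 0.468), with *GPX2* (1.65) and *XBP1* (1.62) at the top and *HSP12* (−1.19) and *AHP1* (−0.93) at the bottom. Amino acid biosynthesis had 18 higher and 11 lower of 70, alike adjusted over the list alone (camera adjusted p = 0.474), from *MET14* (3.28) and *LYS1* (1.35) to *GDH3* (−1.49) and *SER2*. Iron, copper and siderophore uptake had 5 higher and 4 lower of 15, alike adjusted over the list alone (camera adjusted p = 0.843), from *CTR2* (0.83) and *SMF3* (0.72) to *FRE3* (−0.80) and *FET4* (−0.85). Cell wall genes had 5 higher and 3 lower of 21 (6 and 4 adjusted over the list alone; camera adjusted p = 0.5), from *EXG1* (1.18) and *DSE2* (0.90) to *UTR2* (−0.71) and *RLM1* (−0.91). Histones and DNA replication had 2 higher and 4 lower of 32 (2 and 2 adjusted over the list alone; camera adjusted p = 0.463). *HHT1* (0.84) and *HTB2* (0.63) were highest and *RNR3* (−0.89) and *CDC6* (−0.90) lowest; *HTB2* missed the threshold without isolate 2 replicate 2 (adjusted p = 0.0529) and *CDC6* without isolate 1 replicate 1 (0.0585).

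None of the 11 list calls held with an estimated correlation, which the 3 strain means estimate from 1 residual degree of freedom. Estimated over the 6 libraries in 3 groups, a choice made after seeing the data, the adjusted p ran from 0.151 to 0.576.

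**Figure D2:**
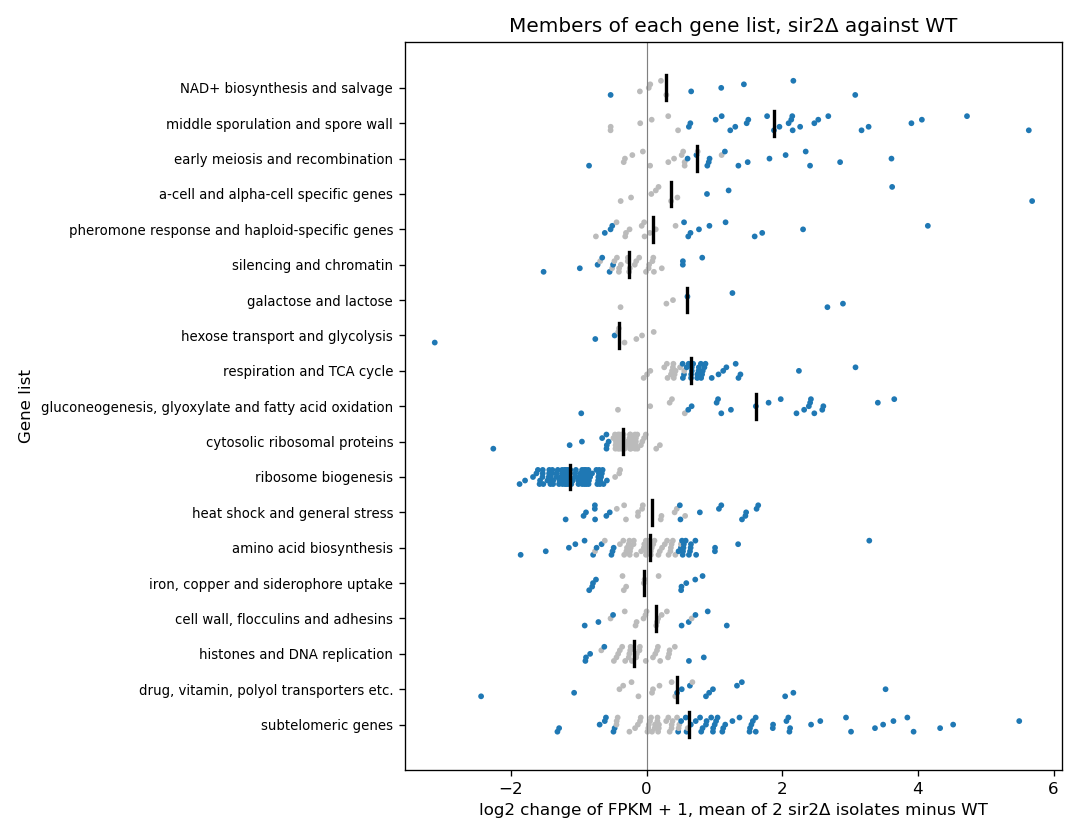
Log2 change (mean of both sir2Δ isolates minus WT, x axis) of each tested member of the 19 gene lists (y axis), blue where the gene passed and grey where it did not, with a black bar at the list median. Ribosome biogenesis lies to the left at a median of −1.13 and middle sporulation to the right at 1.88.

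Genes near chromosome ends rose more often than others. Of 120 terminal genes 84 were tested, and 46 of these (54.8%) were higher and 7 lower, against 19.6% higher among the 4937 other genes (odds ratio 4.97, 95% interval 3.14 to 7.89, Fisher's exact p = 1.72e-12). The median change was 0.63 (48 higher and 9 lower adjusted over the list alone; camera adjusted p = 5.6e-09, adjusted p = 0.819 with an estimated correlation). KLLA0A00132g (5.49) and KLLA0D00187g (4.52) were highest, and *URA1* (−1.31) and KLLA0A12001g (−1.29) lowest. Among tested genes the share of higher genes was 60% of 30 at positions 1 to 5 from an end and 51.9% of 54 at 6 to 10. It was 33.9% of 112 at positions 11 to 20 and 20.8% of 240 at 21 to 40. The filter used the mean over all 3 strains, so a gene silent in WT was tested only if it rose. The shares next to the ends therefore depend on which genes were tested, and a gradient among the terminal genes is not shown. The odds ratio depends on the filter in the same way, since 36 of the 55 untested genes were terminal. Fisher's test also treats genes as independent, while neighbours moved together, so its interval and p-value overstate the certainty. On the right arms of chromosomes B and E, 9 of 9 and 9 of 10 tested terminal genes were higher, against 1 of 10 on the right arm of chromosome C. Of the 36 untested terminal genes, 28 were at 0 in every library, and terminal genes of repeated families can share reads.

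**Figure D3:**
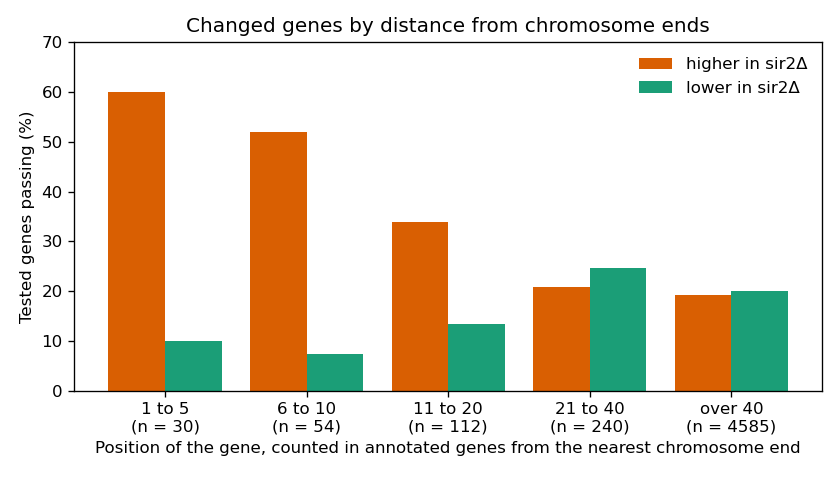
Share of tested genes that were higher (orange) or lower (green) in sir2Δ than in WT, in percent (y axis), by position counted in annotated genes from the nearest chromosome end (x axis, n tested under each bar pair). Among tested genes the higher share was 60% next to the ends (30 tested) and 19.2% beyond 40 genes (4585 tested). A gene silent in WT was tested only if it rose, so the bars next to the ends depend on the filter.

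Changed genes lay near each other in the order of tested genes. Untested genes were skipped, so neighbours in a run need not be adjacent on the chromosome. KLLA0D00187g and KLLA0D00330g, at positions 3 and 11 from the left end of chromosome D, stood in the same run. There were 110 runs of 3 or more neighbours passing in the same direction, 62 of rises and 48 of falls, holding 383 genes, while random gene orders gave 64.5 on average and at most 90 (one-sided permutation p = 1e-04, the smallest that 10000 orders can give). The longest held 10 genes, KLLA0B14729g to KLLA0B14927g (median 1.70), and 9 genes, KLLA0E24861g to KLLA0E25147g (median 1.87). They lie at the right ends of chromosomes B and E, and all but KLLA0B14729g are the terminal genes already counted as higher there. Picked out after their values were seen, *GAL1* and *GAL10* formed a run with KLLA0F08371g (3.91), *PFS1* and *TNA1* flanked *RAD2* (0.52), and *DIT1* and *DIT2* of the spore wall stood in a run of 5 with *URH1*.

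The isolates differed from each other far less than from WT. Isolate 2 was higher than isolate 1 for 396 genes and lower for 541, of which 1 and 8 differed at least 2-fold (limma, 6 libraries). *GAL1* (0.95) and *GAL10* (0.92), KLLA0B12606g (1.05), KLLA0C18931g (0.95) and KLLA0D13310g (0.92) were highest in isolate 2 relative to isolate 1. KLLA0E16149g (−1.32), KLLA0D15565g (−1.11), KLLA0D04181g (−1.06), *DAD4* of the kinetochore (−1.03) and the aldehyde dehydrogenase gene *ALD5* (−1.02) were lowest. Ribosome biogenesis genes were lower in isolate 2 for 54 of 95 and higher for 0 (median −0.38; camera adjusted p = 1.49e-21, adjusted p = 0.431 with an estimated correlation). Galactose and lactose genes were higher for 5 of 7 (median 0.68; camera adjusted p = 1.04e-05, adjusted p = 0.307 with an estimated correlation) and glycolysis genes for 8 of 9 (median 0.43; camera adjusted p = 5.68e-07, adjusted p = 0.502 with an estimated correlation). These list tests between isolates were added after seeing the data. The p-values rest on technical spread, and the 937 calls became 232 without isolate 2 replicate 2, 349 without isolate 1 replicate 1 and 601 without isolate 2 replicate 1.

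Each isolate alone also differed from WT in the fit to 6 libraries: 1548 genes were higher and 1837 lower in isolate 1, and 1648 and 1941 in isolate 2. *IME1*, *AGA2*, *NPT1* and *TNA1* were higher in both isolates and *ADH3* and *SDA1* lower in both.

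**Figure D4:**
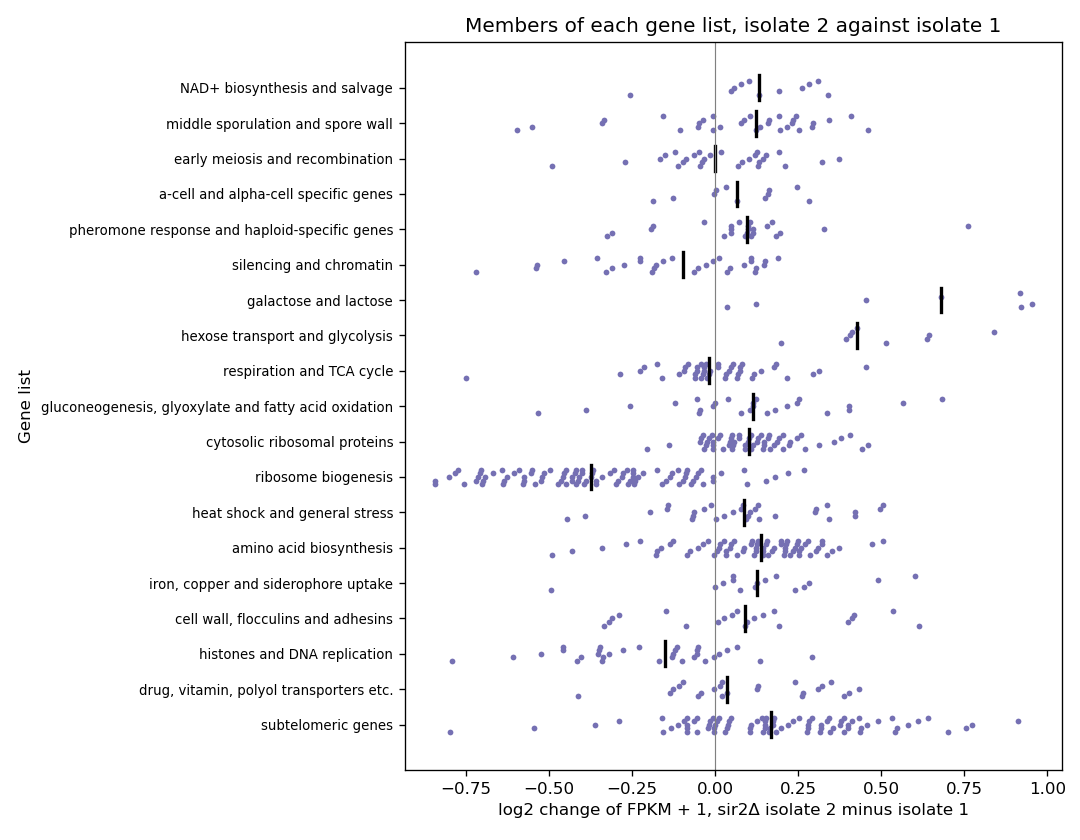
Log2 difference of sir2Δ isolate 2 minus isolate 1 (x axis) for each tested member of the 19 lists (y axis), 1 point per gene, with a black bar at the list median. The galactose list has the highest median, 0.68, and ribosome biogenesis the lowest, −0.38.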

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

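The tests of scaling, growth state, whole-chromosome change and sporulating cells were chosen only after the results were seen, as were all list comparisons between the isolates; the tests of expression level, coding length and shared reads were written down before.

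The isolates share a genotype label and still differed in 937 genes by the limma contrast between them, and the values here are log2 differences of isolate 2 minus isolate 1. That count was 232 without isolate 2 replicate 2, 349 without isolate 1 replicate 1 and 601 without isolate 2 replicate 1. By camera, 9 lists differed: galactose and lactose (median 0.68), hexose transport and glycolysis (0.43), subtelomeric genes (0.17), amino acid biosynthesis (0.14), NAD+ biosynthesis and salvage (0.13), iron, copper and siderophore uptake (0.12), cytosolic ribosomal proteins (0.10), histones and DNA replication (−0.15) and ribosome biogenesis (−0.38). None held with an estimated correlation. The ribosomal protein call was lost without isolate 2 replicate 2 (adjusted p = 0.45), the amino acid call without isolate 1 replicate 1 (0.13), and the iron call without isolate 1 replicate 1 (0.13) or isolate 2 replicate 1 (0.0526). The NAD+ call was lost without WT replicate 1 (0.0714), WT replicate 2 (0.0715), isolate 1 replicate 1 (0.0709) or isolate 2 replicate 2 (0.103).

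Of the 105 genes named by rule, 41 differed between isolates, 21 higher and 20 lower in isolate 2. Higher were KLLA0B12606g (1.05), *GAL1* (0.95), KLLA0C18931g (0.95), KLLA0D13310g (0.92), *GAL10* (0.92), *ADH3* (0.84), *CLN3* (0.76), *GAL7* (0.68), *POX1* (0.56), *PGI1* (0.51), *MOH1* (0.43), *AHP1* (0.42), *GPM1* (0.41), *FBA1* (0.41), *DSE2* (0.40), KLLA0D00187g (0.40), *URA1* (0.34), *POS5* (0.34), *RRT8* (0.32), *TNA1* (0.31) and *SMF3* (0.28). Lower were KLLA0E16149g (−1.32), KLLA0D15565g (−1.11), KLLA0D04181g (−1.06), *DAD4* (−1.03), *ALD5* (−1.02), KLLA0F07073g (−0.86), *CDC6* (−0.79), *PCL1* (−0.74), *FOB1* (−0.72), *SDA1* (−0.71), *SHC1* (−0.60), KLLA0A07777g (−0.52), *MSH5* (−0.49), *DBP8* (−0.46), *RNR3* (−0.41), *TRM44* (−0.40), *ALD4* (−0.39), *RCM1* (−0.36), *CHS3* (−0.34) and *EXG1* (−0.31).

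Ribosome biogenesis genes were lower in sir2Δ than in WT (median −1.13) and lower in isolate 2 than in isolate 1. Mean expression level and coding length do not account for the fall from WT, since the lowest of 10000 random lists matched on both had a median of −0.33. That mean included the sir2Δ strains, so the level in WT alone was not matched. The median of all genes was −0.058, but the values came already scaled, which can itself set that median. It therefore cannot test the authors' scaling. A shift common to all genes would not place this list below the others, but the size of the fall depends on the scaling. A gained or lost chromosome in 1 isolate is excluded for the difference between isolates, because chromosome medians departed from 0 by at most 0.032 and the list was lower on all 6 chromosomes. A difference in growth state between cultures cannot be told apart from the deletion, since each strain was 1 culture, and the list differed by −0.38 between isolates of the same genotype. The genotype itself stays an open explanation.

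Middle sporulation genes were higher in sir2Δ (median 1.88), and the highest of 10000 lists matched on mean level and coding length reached 0.54, which argues against those properties. That mean included the sir2Δ strains, so a low level in WT was not matched and stays open. The counts alone cannot tell a share of sporulating cells in the sir2Δ cultures apart from raised expression in all cells. Of 28 early meiosis genes 14 were higher, *SPO13* was lower, and the stage of such cells is unknown. By their genotype labels all strains are *MATa* without *HML* and *HMR*. The cultures thus lack the alpha information of a/alpha cells, the type that usually sporulates. Whether any cell sporulated was not measured. The genotype stays open, as untested.

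Subtelomeric genes were higher in sir2Δ (median 0.63), and the highest of 10000 lists matched on mean level and coding length reached 0.29. Mean level and coding length therefore do not account for the rise. That mean included the sir2Δ strains, so the rise itself entered the matching. A low level in WT was not matched, and the test cannot decide whether it accounts for the rise. The 50 terminal genes that have the coding length of another terminal gene, 20 of them tested, were left out. The odds ratio of higher calls was then 4.1 (32 of 64 higher, Fisher's exact p = 6.32e-08). Fisher's test again treats genes as independent and covers tested genes only. The bound set beforehand for excluding shared reads was met, but it was a poor bound: equal length finds only copies that kept their length, and no genome sequence was used here to find others. Shared reads therefore cannot be told apart from separate rises for part of these genes. The genotype stays open, as untested.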

How the results depend on the processing

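The list tests with an estimated correlation over 6 libraries and with 6 libraries in 2 groups without a block, and all alternatives for lists between isolates were chosen after seeing the data. No called gene among the 105 named changed direction under any alternative run. Of 2179 alternative values of these genes, 2056 kept direction and side of the threshold, 14 (5 genes) lost their call, 93 (22 genes) gained one and 16 (8 genes) changed sign without being called before or after; 20 called genes changed less than 2-fold. The counts of higher and lower genes stayed within 1.5 times of the reported 1013 and 1000 under every pseudocount, filter, scaling, variance setting and left-out library; rises made up 50.3% of calls, 44.2% after quantile normalization and 55.8% with medians made equal. Depth is unknown, so its limits on low genes could not be given. Genes within 20 kb of a chromosome end were not run, because the build is not stated.

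Fits that entered technical libraries singly gave higher counts. With 6 libraries in 2 groups there were 1477 higher and 1740 lower genes, with the replicate number as a block (replicate block) 1443 and 1675, and in 3 strain groups 1667 and 2026, and each of these sets included all 2013 reported genes in the same direction. With the within-strain correlation estimated there were 1302 and 1474, which included 2008 of them. Isolate 1 alone gave 1548 and 1837, isolate 2 alone 1648 and 1941, and the 2-fold limit left 457 and 308. The fits to single libraries count technical libraries as replicates, which adds degrees of freedom and brings technical spread into the error. The median SE was 0.097 for each isolate against WT in the 6-library fit and 0.165 on strain means. With all 6 libraries the fold changes of both isolates against WT equal those on strain means by design. The shared directions are therefore no separate support. Deviations of same-numbered libraries hardly correlated between WT and isolates 1 and 2 (0.005 and 0.055). Between the 2 isolates they correlated weakly (0.206), so pairing by replicate number is not excluded there. With 6 libraries in 2 groups the galactose list missed the threshold without a block (adjusted p = 0.0827) and with the replicate block (0.0836), and the uncalled iron list turned sign in both (0.978 and 0.986). The block itself changed no list call, and no other list call changed in these 2 fits.

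The a-cell and alpha-cell list missed the threshold at a mean of at least 10 FPKM (0.102), where fewer genes were tested. Hexose transport and glycolysis passed after quantile normalization (0.0374), and with each library left out its adjusted p ran from 0.022 to 0.131. The uncalled amino acid list turned sign after quantile normalization (0.992) and without isolate 1 replicate 2 (range 0.233 to 0.906). The cause was not tested.

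With an estimated correlation on 3 strain means, adjusted p was 0.769 for middle sporulation, early meiosis, respiration and gluconeogenesis, 0.819 for the a-cell and alpha-cell, ribosome biogenesis, transporter and subtelomeric lists, and 0.844 for NAD+, galactose and ribosomal proteins. On 6 libraries it was 0.151 for middle sporulation, 0.256 for early meiosis, 0.325 for respiration, gluconeogenesis, ribosome biogenesis and subtelomeric genes, 0.337 for galactose, 0.483 for the a-cell and alpha-cell list, 0.53 for NAD+ and transporters and 0.576 for ribosomal proteins. The rotation test fry, which asks whether a list's genes move to 1 side on balance, gave 0.0846 for early meiosis, 0.111 for middle sporulation, 0.134 for gluconeogenesis and the a-cell and alpha-cell list, 0.2 for NAD+, transporters and subtelomeric genes, 0.259 for ribosomal proteins and ribosome biogenesis and 0.443 for galactose; respiration passed (0.0148). Both tests have 1 residual degree of freedom on strain means.

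Between isolates, an estimated correlation gave 0.307 for galactose and for histones and replication, 0.431 for ribosome biogenesis and subtelomeric genes, 0.502 for glycolysis, 0.522 for iron, 0.584 for NAD+, 0.597 for amino acids and 0.634 for ribosomal proteins. With each library left out, adjusted p ran from 4.51e-06 to 0.13 for amino acids, 1.92e-08 to 0.45 for ribosomal proteins, 0.00852 to 0.13 for iron and 0.00787 to 0.103 for NAD+. The count of differing genes ran from 232 (without isolate 2 replicate 2) to 918.

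The sign changes of uncalled genes were as follows. After quantile normalization *PGI1* was at 0.009, *ATP20* at −0.20 and KLLA0E16149g at −0.40, and with equal medians *ATP7* was at 0.005. With each library left out, KLLA0E16149g ran from −0.17 (without WT replicate 1) to 0.635, *ATP20* from −0.006 to 0.021 and *ATP7* from −0.096 to 0.012. Isolate 1 alone gave *GAL7* −0.047, *FBA1* −0.10 and *ATP7* 0.012, and isolate 2 alone *POS5* 0.072, *PGI1* 0.19, *ATP20* −0.02, KLLA0B12606g 0.26 and KLLA0E16149g −0.42.

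The subtelomeric odds ratio and the excess of runs passed under every alternative run for them, and *SIR2* changed by −5.97 to −5.93 with each library left out.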

Other observations

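Groups of genes sharing a symbol prefix were compared after seeing the data, 68 in all. These include 2 merged groups, proteasome subunits and mitochondrial ribosomal proteins, some of whose prefixes were also tested alone, so the groups overlap. None kept its call with an estimated correlation over the 6 libraries (adjusted p = 0.571 for each family whose values follow). Autophagy genes (*ATG*) were higher in 18 of 32 and lower in 0 (median log2 change 0.70, camera adjusted p = 3.84e-06), led by *ATG45* (2.78), *ATG10* (2.15) and *ATG8* (2.06), whose product coats autophagosome membranes. Proteasome genes were higher in 11 of 34 and lower in 0, with a small median of 0.35 (camera adjusted p = 0.000997). They were also higher in isolate 2 than in isolate 1 (median 0.097, camera adjusted p = 0.0172 at the preset correlation).

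Ergosterol genes (*ERG*) were lower in 10 of 20 and higher in 0 (median −0.45, camera adjusted p = 0.000778), with *ERG1* (−1.895), *ERG3* (−1.53), *ERG2* (−1.51) and *ERG11* (−1.49), the azole target, lowest. RNA polymerase subunit genes named *RPC* were lower in 9 of 11 (median −1.05, camera adjusted p = 0.000697), and tRNA methyltransferase genes (*TRM*) in 10 of 14 (median −0.91, camera adjusted p = 0.000997). Both families were also lower in isolate 2 than in isolate 1, which share a genotype (*RPC* median −0.23, camera adjusted p = 0.000608; *TRM* median −0.33, camera adjusted p = 0.000348, at the preset correlation). For these family differences between isolates, neither an estimated correlation nor leaving out libraries was run.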
